A study of Mus musculus with 25 samples.

How the data were processed

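Adult mouse testis cells of 25 libraries in 5 groups were measured by Drop-seq. Cells were dissociated with collagenase and then trypsin, and live cells were sorted by dye exclusion. Haploid cells were depleted by Hoechst staining in 2 libraries. Spermatogonia were enriched through a fluorescent label on the Gfra1 lineage or a Kit antibody, interstitial cells through Thy1 or Sca1 antibodies, both, or a collagenase supernatant, and Sertoli cells through a label on the Amh lineage or a Sox9 reporter. The labels give ages of 7 to 20 weeks and the strain C57BL/6 for all libraries, and the protocol also mentions transgenic mice. Of the libraries 17 held spike-in cells of another species, which the authors used to measure doublets, and 8 did not. The species was macaque (Macaca mulatta) in Sertoli-enriched replicates 5, 6 and 8 and human in the rest of the 17. No further removal of doublets was made here.

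The count tables hold UMI counts per gene and barcode as deposited, which the authors made with STAR 2.5.2b, Picard 2.6.0 and SAMtools 1.2 on GRCm38, together with GRCh37 for the mixed libraries. The percent values of the deposited annotation table (mitochondrial and X-linked percent per cell) were computed by the authors from those counts. The authors kept cells with over 500 genes and under 10% mitochondrial counts. The retained cells here had at least 501 genes and at most 9.99% mitochondrial counts, and the summed counts of all 34633 cells equalled the deposited UMI numbers. The X-linked percent computed here and the deposited one had a Pearson r of 0.9958 over cells. Of 59854 deposited barcodes 25221 were not retained by the authors and were left out. Cell classes were the authors' 11 annotated classes. Their label "STids" was treated as round spermatids, and cells annotated as unknown were called unknown somatic. A further 18 columns of the annotation table were not used here.

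Of 37443 gene symbols 91.8% were placed on 1 chromosome in GENCODE M21, and they held 96.4% of counts, with 1994 X-linked and 31702 autosomal genes. Coordinates are those of GRCm38. Reads of near-identical gene copies cannot be told apart in counts per gene.

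Cells are not replicates, so counts were summed per library and class, with at least 20 cells per sum. For Sertoli and Leydig cells between groups, where 20 left too few whole-testis sums, at least 10 cells were used, one of the alternatives set beforehand. Sums were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test after filterByExpr and TMM scaling, with the library as a block between classes. Between classes a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg) and a change of at least 2-fold, and between groups at an adjusted p under 0.05. Each germ cell class was compared with the one before it, and each of 5 somatic classes with the mean of the other 4. Groups were compared with whole testis within a class. Comparisons, thresholds, gene lists and the alternatives, except those named as added later, were set before the data were examined.

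The 23 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. They were undifferentiated spermatogonia, differentiating spermatogonia, meiotic prophase, acrosome and round spermatid, nuclear condensation and sperm tail, Sertoli, Leydig steroidogenesis, peritubular myoid contractile, macrophage, innate lymphoid and T cell, endothelial, interstitial mesenchyme, erythrocyte, dissociation stress, cell cycle, retinoic acid pathway, niche ligands, niche receptors, X-linked glycolysis genes and autosomal testis copies, piRNA pathway, ribosomal proteins, mitochondrially encoded and X-linked genes. Counts of list members are over all genes tested unless stated as adjusted over the list alone.

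Genes were named by rule. For each germ cell step these were the 6 rising and 6 falling called genes with the largest fold among genes with a mean of at least 100 CPM (counts scaled to a common library total) in the higher class and the same sign in every library holding both classes. For each somatic class they were the 4 higher called genes of largest fold, and for each comparison of groups the 5 rising and 5 falling called genes of smallest p. Names of the forms Gm and Rik and mitochondrial genes were left out, and the 4 members of highest mean CPM of each list that bears on the comparison were added. A gene that the rule names is not reported here, and its values, 2 of which reversed under an alternative, are left out of the counts of alternatives. Genes named outside this rule are list members, or are said to be chosen after their values were seen.

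Shares of cells between groups were compared with two-sided exact permutation tests of the difference in means, and values of classes within libraries with two-sided exact sign flip tests. Genes per cell were counted after thinning each cell with at least 1000 UMIs to that number. Fewer UMIs were held, and so left out here, by 1336 of 4239 spermatogonia, 768 of 8792 spermatocytes, 1059 of 9923 round and 537 of 6598 elongating spermatids. A fold against a group with no counts was computed against a floor of 3 counts over the group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

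Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, other cell minimums (10 and 50), no library block, the replicate number as a block, leaving out libraries, thinning, and subsets of libraries. Library totals without a scaling factor and subsets by spike-in species were among those added after seeing the data. For the comparisons of fitted gene counts, up to 100 other splits of the sums were fitted, 50 per germ cell step and 30 for the somatic sums.

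Precision was tested on simulated data with 200 changed genes per comparison and the depths and numbers of sums used here. At 1.5, 2 and 4-fold, edgeR recovered 3.03%, 44.6% and 100% of changed genes from spermatogonia to spermatocytes, 0%, 50.8% and 100% to round spermatids and 0%, 50.9% and 100% to elongating spermatids. The somatic values were 6.25%, 36.2% and 83.1% for endothelial cells, 4.35%, 24.5% and 82.0% for Leydig cells, 4.26%, 14.0% and 77.6% for macrophages, 0%, 0% and 15.5% for Sertoli cells and 2.33%, 33.9% and 91.5% for unknown somatic cells. Between groups they were 2.94%, 12.1% and 96.5% for spermatogonia, 26.0%, 59.3% and 91.8% for spermatocytes, 3.45%, 14.8% and 87.2% for Sertoli cells, 1.39%, 9.30% and 76.6% for Leydig cells, 38.6%, 74.6% and 100% for unknown somatic cells and 24.6%, 84.7% and 100% for elongating spermatids. False calls numbered 0 in each germ cell step, at most 5 in a somatic class and at most 9 in a comparison of groups. Between classes a call needed a fitted change of at least 2-fold, which limits recovery at 1.5 and 2-fold. The simulated data held no library effects or correlated genes, and far fewer changed genes than were called in the germ cell steps. Their false calls need not carry over to the real data.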

Results

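Drop-seq, which captures single cells with barcoded beads in droplets and counts each transcript once through a unique molecular identifier (UMI), was applied to adult C57BL/6 mouse testis in 25 libraries. The labels put 6 libraries in whole testis with no enrichment, 2 in a group depleted of haploid cells by Hoechst staining, 3 in a spermatogonia-enriched group, 6 in an interstitial-enriched group and 8 in a Sertoli-enriched group. The authors retained 34633 cells with 214891204 UMIs. Whole-testis libraries held 11554366 to 21063122 UMIs each, haploid-depleted libraries 5887981 to 7766430, spermatogonia-enriched libraries 4298770 to 12151452, interstitial-enriched libraries 1161486 to 10734211 and Sertoli-enriched libraries 1106533 to 10445613. The number of retained cells ranged from 81 to 3047 per library and the median UMIs per cell from 1422 to 10634. The labels do not tie libraries to animals, so p-values measure the spread between these libraries, which may in part be technical.

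Germ cells made up 96.7% ± 1.06 (SD, n = 6 libraries) of whole-testis cells. Round spermatids (39.3% ± 4.77) and spermatocytes (39.0% ± 3.38) were the most frequent classes, followed by elongating spermatids (9.91% ± 1.33) and spermatogonia (8.53% ± 3.91). Among somatic classes, the cells that the authors left unnamed (unknown somatic) took 1.97% ± 0.643, Sertoli cells, which nurse the germ cells inside the tubules, 0.664% ± 0.330, Leydig cells, which make testosterone, 0.409% ± 0.159 and endothelial cells 0.193% ± 0.238. Over all libraries the authors' annotation gave 8792 spermatocytes, 9923 round spermatids, 6598 elongating spermatids, 4239 spermatogonia, 2205 unknown somatic cells, 2131 Sertoli cells, 314 Leydig cells, 179 endothelial cells, 139 macrophages, 64 innate lymphoid cells and 49 peritubular myoid cells.

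The first comparison asked how far each selection shifted the class it was aimed at. Sertoli cells made up 23.8% ± 9.12 (SD, n = 8) of cells in Sertoli-enriched libraries against 0.664% ± 0.330 (n = 6) in whole testis, 35.9-fold higher, and 8 of 8 libraries lay above every whole-testis library. The non-germ, non-Sertoli classes together made up 43.3% ± 38.9 (n = 6) in interstitial-enriched libraries against 2.61% ± 0.799 (n = 6), 16.6-fold higher, with 6 of 6 libraries above every whole-testis library. Spermatogonia made up 91.7% of the library selected with an antibody to Kit, a receptor of differentiating spermatogonia, but 11.8% and 9.93% of the libraries selected by a fluorescent label on the Gfra1 lineage, against 8.53% ± 3.91 (n = 6) in whole testis. Round and elongating spermatids together made up 16.0% and 29.9% of the haploid-depleted libraries against 49.2% ± 4.73 (n = 6).

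By exact permutation tests of the difference in mean share (two-sided, 4 tests, Benjamini-Hochberg adjustment), the Sertoli-enriched group (p = 0.000666, adjusted p = 0.00266) and the interstitial-enriched group (p = 0.00216, adjusted p = 0.00433) differed from whole testis, each at the smallest p its design allows. The spermatogonia-enriched group did not (exact p = 0.167, smallest possible 0.0238, adjusted p = 0.167), and without the Kit library (replicate 3) its excess fell from 29.3 to 2.34 points. The haploid-depleted group, 26.3 points lower in mean, could not pass in a design of 2 against 6 libraries (exact p = 0.0714, the smallest possible, adjusted p = 0.0952). Among libraries with human spike-in cells alone, the excess was 34.6 points for the interstitial classes (exact p = 0.133) and 21.01 points for Sertoli cells (exact p = 0.0952), each the smallest p these fewer libraries allow, and without spike-in cells it was 53.1 points for the interstitial classes. Within the interstitial-enriched group, shares were 99.2% and 74.9% after Sca1 selection, 55.3% and 10.6% after Thy1 selection, 12.2% after both and 7.85% in a collagenase supernatant. These libraries were of 9 to 18 weeks and the Kit library of 20, against 7 and 9 weeks in whole testis. Age was not tested for these shares. Sertoli cells made up 19.9% to 37.7% of the libraries labelled on the Amh lineage and 6.01% and 20.6% of those labelled through Sox9.

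**Figure D1:**
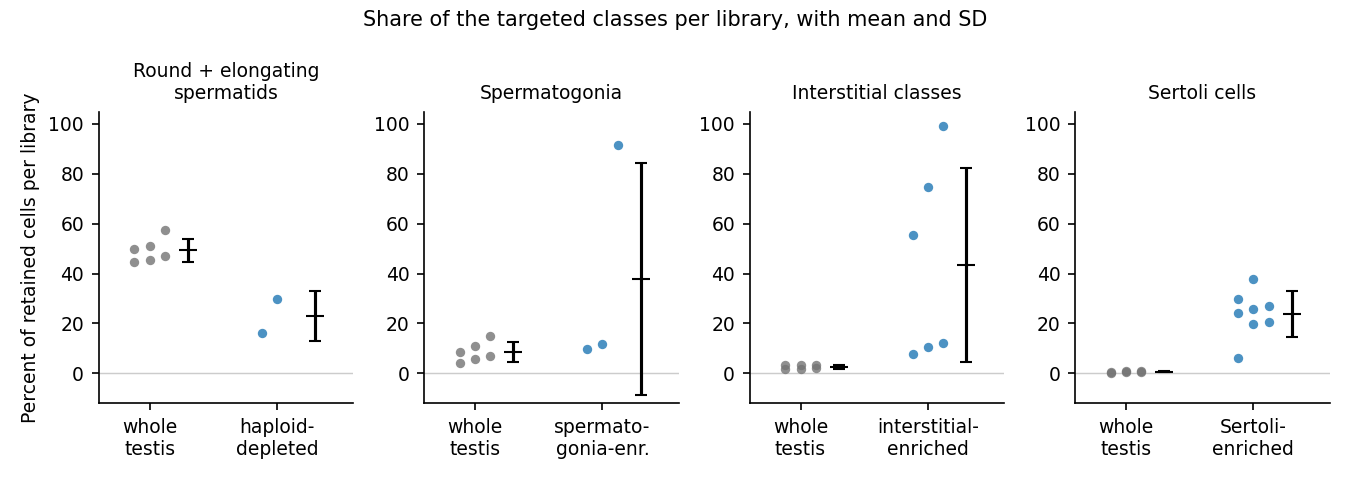
Percent of retained cells in the classes each selection was aimed at, with 1 point per library and bars for the mean and SD, in whole testis and in the enriched or depleted group. All 8 Sertoli-enriched libraries and all 6 interstitial-enriched libraries lay above the whole-testis libraries, while 1 of the 3 spermatogonia-enriched libraries reached 91.7%.

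Gene changes along spermatogenesis were measured between successive germ cell classes within libraries, in counts summed per library and class. The classes rest on the same RNA counts, so these contrasts describe the classes and are not independent evidence for them. From spermatogonia to spermatocytes, most listed genes of spermatogonia fell. With TMM scaling most listed genes of the acrosome and of round spermatids rose. None of these list calls held with an estimated correlation. Stra8, which the retinoic acid signal switches on before meiosis (chromosome 6, 34920163 to 34939344, GRCm38), fell from 843.9 ± 329 CPM (SD, n = 21 libraries) to 0.693 ± 1.12 (n = 20), a log2 change of -9.38 ± 0.26 (SE). The log2 change was -8.57 for Crabp1, which binds retinoic acid, -8.51 for Cenpa, the centromeric histone, -8.33 for Igfbp2, -8.20 for Cdca7 and -8.07 for Ccnd1, a cyclin of the G1 phase. Ppp3r2, a testis form of the regulatory calcineurin subunit (chromosome 4, 49678747 to 49682024), rose from 98.8 ± 75.8 to 1507 ± 177 CPM (log2 change 4.53 ± 0.18). Rasl2-9 (chromosome 7, 5124938 to 5125950) rose by 4.70 ± 0.17 on the log2 scale, Tomm20l by 4.64, RP23-50I16.2 by 4.59, Ube2d2b by 4.56 and Ghrl by 4.53. The naming rule took only genes that moved the same way in all 19 libraries that held both classes, so this agreement is no test.

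Among the lists fixed before the data were examined, 12 of 13 differentiating spermatogonia genes fell (camera adjusted p = 7.77e-07; adjusted p = 0.123 with an estimated correlation). Uchl1 gave -5.75 on the log2 scale and Tex15, which acts in meiotic recombination, -4.21, while Dmrtb1, a transcription factor at the turn from mitosis to meiosis, rose by 3.11. Of 6 undifferentiated spermatogonia genes, 5 fell, Zbtb16 by -5.12 and Foxo1 by -4.71, and Id4 rose by 1.66, in 18 of 19 libraries (adjusted p = 0.0428; adjusted p = 0.278 with an estimated correlation). Of 9 retinoic acid genes 7 fell and 2, Rdh11 and Aldh1a2, rose (adjusted p = 0.0482; adjusted p = 0.278 with an estimated correlation), and of 8 niche receptors 6 fell, Kit among them (adjusted p = 0.0349; adjusted p = 0.278 with an estimated correlation). Of 26 acrosome and round spermatid genes, 20 rose (adjusted p = 0.00184; adjusted p = 0.414 with an estimated correlation), with log2 changes of 3.68 for Spink2, 3.53 for Dkkl1 and 3.94 for Zpbp2. Of 11 glycolysis genes 8 rose, Ldhc, the testis lactate dehydrogenase, from 1040.4 ± 1008 to 7530 ± 1087 CPM (adjusted p = 0.0446; adjusted p = 0.414 with an estimated correlation).

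Of 29 meiotic prophase genes, 9 rose and 9 fell, Syce1 by +2.25 and Sycp1 by -1.47, both parts of the synaptonemal complex that holds paired chromosomes, and the list did not pass (adjusted p = 0.98). Its median was -0.26 while the test pointed up. Of 17 genes of the piRNA pathway, which silences transposons in the germ line, 9 rose and 3 fell (adjusted p = 0.0673), with Mael at 2.49 and Gtsf1 at 2.52. Of 87 ribosomal protein genes, 36 fell and 3 rose (adjusted p = 7.77e-07; adjusted p = 0.414 with an estimated correlation), and 12 of 12 mitochondrially encoded genes fell (adjusted p = 0.00187; adjusted p = 0.414 with an estimated correlation). Of 18 cell cycle genes 7 fell and 2, Ccnb2 and Birc5, rose (adjusted p = 0.0647). The protamine genes Prm1 and Prm2, whose products pack sperm DNA, were at 920.5 ± 1038 and 840.5 ± 931 CPM in spermatogonia and at 454.8 ± 489 and 472.6 ± 615 in spermatocytes, and were not called. Sertoli genes fell in 9 of 10 cases (adjusted p = 0.0241; adjusted p = 0.414 with an estimated correlation), Clu from 129.7 to 24.7 CPM, and so did 5 of 8 dissociation stress genes (adjusted p = 0.105). In Sertoli-enriched libraries the Sertoli genes counted as background below gave 6.42 ± 3.07 UMIs per spermatogonium and 6.43 ± 6.22 per spermatocyte. The fall in share was there no fall per cell.

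In all, 3497 genes were higher and 2871 lower in spermatocytes among 10638 tested by edgeR's quasi-likelihood test at an adjusted p under 0.05 and at least a 2-fold change. The balance moved with the scaling: 2178 were higher and 4448 lower with DESeq2 size factors, and 2475 higher and 4036 lower with library totals, as the median log2 change over all genes moved from 0.16 to -0.64 and -0.46. Acrosome genes that rose numbered 10 rather than 20 under either of these scalings, and ribosomal protein genes kept a median below 0 under each.

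From spermatocytes to round spermatids, most listed genes of the acrosome, of sperm nuclear packing and of the sperm tail rose. Most X-linked genes came up, and of 29 genes of meiotic prophase 16 fell and 6 rose. None of these list calls held with an estimated correlation. Ccdc27 (chromosome 4, 154026639 to 154042677) rose from 2.15 ± 1.87 CPM (n = 20 libraries) to 138.8 ± 26.5 (n = 22), a log2 change of 6.31 ± 0.17. Tex29 rose by 6.11, Cct8l1 by 6.10, Hyal5, a sperm hyaluronidase, by 6.06, Micalcl by 6.05 and Dscc1 by 6.05. Phf2, a histone demethylase (chromosome 13, 48801750 to 48871119), fell from 183.3 ± 27.6 to 3.10 ± 1.93 CPM (log2 change -5.38 ± 0.19), as did Pou5f2 (-5.33), Gmnn, an inhibitor of DNA replication licensing (-4.98), Ube2t (-4.88), Lsm3 (-4.79) and Dut (-4.75). By the naming rule these 12 genes had to move the same way in all 20 libraries that held both classes.

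Of 20 nuclear condensation and sperm tail genes 19 rose and none fell (camera adjusted p = 7.95e-06; adjusted p = 0.553 with an estimated correlation). Prm1 rose from 454.8 ± 489 to 4414 ± 3170 CPM (log2 change 4.08 ± 0.32), Prm2 by 3.96, and the transition protein genes Tnp1 and Tnp2, whose products replace histones ahead of protamines, by 4.73 and 4.31. Of 26 acrosome and round spermatid genes 20 rose, Tssk2, a testis kinase, by 5.18 (adjusted p = 2.21e-07; adjusted p = 0.533 with an estimated correlation), while Spink2 gave -0.08 ± 0.20 and was not called. Of 331 X-linked genes 274 rose and none fell (adjusted p = 4.66e-15; adjusted p = 0.533 with an estimated correlation), Akap4, the main protein of the fibrous sheath (chromosome X, 7067519 to 7078609), by 5.04, Cypt1 by 5.12 and the histone variant gene H2afb1 by 4.74. Meiotic prophase genes fell in 16 of 29 cases and rose in 6 (adjusted p = 0.0338; adjusted p = 0.553 with an estimated correlation), Sycp2 by -2.06, and of 17 piRNA pathway genes 9 fell and 1, Gtsf1, rose (adjusted p = 0.0338; adjusted p = 0.553 with an estimated correlation). Of 18 cell cycle genes 8 fell and 1 rose (adjusted p = 0.0647), Cdc20, an activator of the anaphase-promoting complex, by -1.87. Of 12 mitochondrially encoded genes 10 fell (adjusted p = 0.0378; adjusted p = 0.611 with an estimated correlation).

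Gapdhs, the sperm glyceraldehyde-phosphate dehydrogenase, rose by 4.63 and Pgk2, an autosomal copy of the X-linked Pgk1, by 1.56, among 5 of 11 glycolysis genes that rose (adjusted p = 0.0766). Ribosomal protein genes stayed near 0 in median (0.00), with 1 up and 8 down of 87 (adjusted p = 0.243), and their median was -0.25 with DESeq2 size factors and -0.46 with library totals. The test called 3353 genes higher and 2616 lower in round spermatids. With library totals these numbers were 2960 and 3632, at a median over all genes of -0.44 instead of -0.00, and with DESeq2 size factors the median was -0.23.

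From round to elongating spermatids, transcripts for the packing of the sperm nucleus came to dominate and most listed acrosome genes fell. Neither list call held with an estimated correlation. Prm1 (chromosome 16, 10796326 to 10805839) rose from 4414 ± 3170 CPM (n = 22) to 54736 ± 8530 (n = 21), a log2 change of 4.83 ± 0.31, and its neighbours Prm2 (chromosome 16, 10791380 to 10796134) and Tnp2 (chromosome 16, 10787936 to 10788660) rose by 4.74 and 4.21. Tnp1 rose by 4.18, Car2, a carbonic anhydrase, by 4.74, Klk1b8 by 4.57, Cyp2a12 by 4.56 and Cby3 by 4.52. Spaca1, a membrane protein of the acrosome (chromosome 4, 34024874 to 34050191), fell from 796.6 ± 117 to 16.9 ± 10.1 CPM (log2 change -4.62 ± 0.18). Glipr1l1 (-4.82), Efhb (-4.78), Prr27 (-4.74), Lrrc34 (-4.66) and Nipsnap3a (-4.64) also fell. The genes of largest fold had to move the same way in all 20 libraries that held both classes to be named.

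Of 20 nuclear condensation and sperm tail genes 17 rose (camera adjusted p = 2.27e-08; adjusted p = 0.444 with an estimated correlation), and of 26 acrosome genes 20 fell and 2 rose (adjusted p = 9.02e-07; adjusted p = 0.444 with an estimated correlation), Zpbp2 by -3.79, Spink2 by -2.36 and Tssk2 by +1.79. Of 11 glycolysis genes 7 rose and 2 fell (adjusted p = 0.0475; adjusted p = 0.444 with an estimated correlation), Gapdhs by 2.88, while Ldhc gave -0.06 ± 0.20. The 12 mitochondrially encoded genes rose (adjusted p = 0.00129; adjusted p = 0.444 with an estimated correlation), and of 18 cell cycle genes 8 fell and 2 rose (adjusted p = 0.0475; adjusted p = 0.444 with an estimated correlation), Ccnb2 by -3.78. Of 18 macrophage genes listed only 4 passed the filter on low counts in germ cells, so they do not stand for the list. These 4 rose, and this call held with an estimated correlation (adjusted p = 0.00129; adjusted p = 0.0235 with an estimated correlation). They were Aif1, an actin-binding protein, at 1847 CPM in elongating spermatids, Apoe, which carries lipids, at 92.9, the complement gene C1qb at 28.7 and the antigen-presenting gene H2-Ab1 at 27.5. Of 10 Sertoli genes 9 rose (adjusted p = 0.0305; adjusted p = 0.444 with an estimated correlation), Clu from 28.7 to 47.4 CPM, against 8403 ± 2647 CPM in Sertoli cells. Per cell the Sertoli genes counted as background below were fewer, at 4.26 ± 3.16 UMIs per round and 2.59 ± 1.93 per elongating spermatid in Sertoli-enriched libraries.

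Ribosomal protein genes had a median change of 0.83, and 31 of 87 rose and 5 fell (adjusted p = 9.02e-07; adjusted p = 0.521 with an estimated correlation), but with library totals the median was -0.07, 3 rose and 16 fell. Of 331 X-linked genes 128 rose and 102 fell (adjusted p = 0.275), with a median of 0.30 and a mean of -0.06, and the median was -0.65 with library totals. Medians also changed sign with library totals for the differentiating spermatogonia, meiotic prophase and retinoic acid lists. The test called 2558 genes higher and 3072 lower in elongating spermatids, and with library totals 1036 and 5396, at a median over all genes of -1.03 instead of -0.07. Adjusted over the list alone, the counts of every list in the 3 germ cell steps were equal to those over all genes tested.

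**Figure D2:**
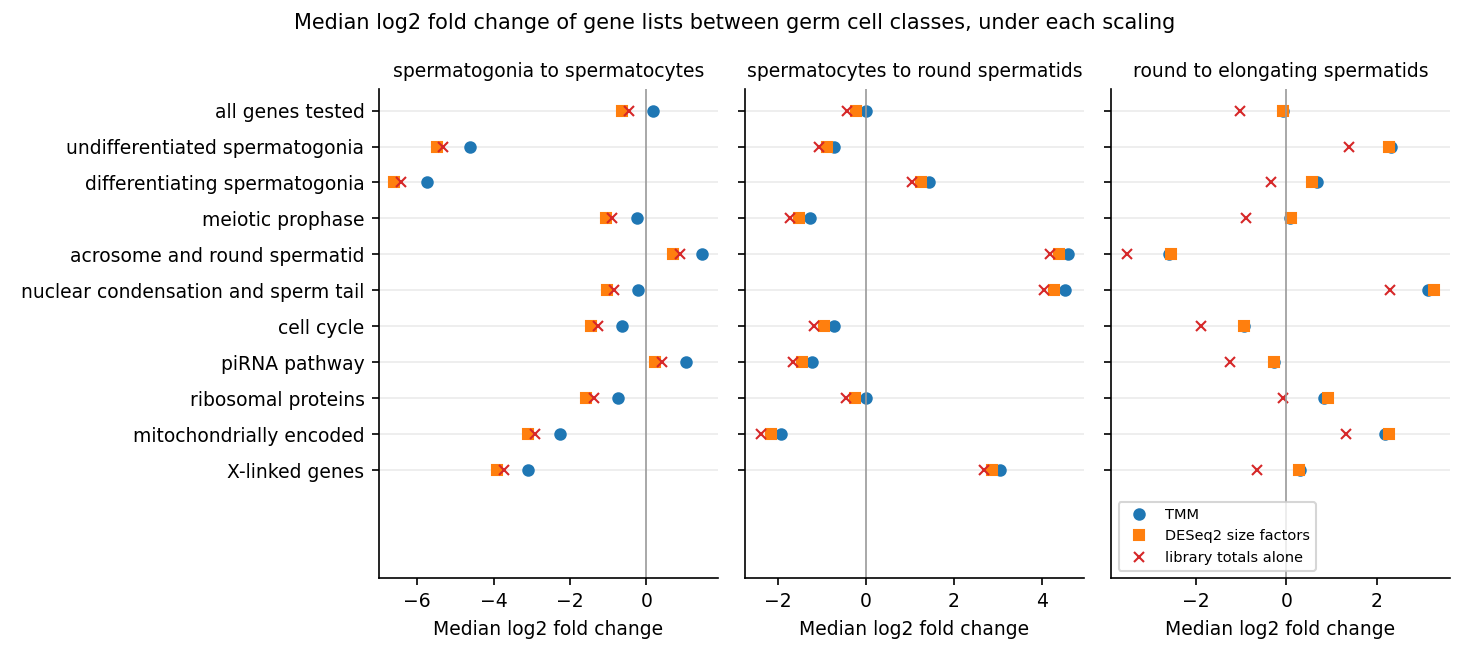
Median log2 fold change of fixed gene lists and of all genes tested at each germ cell step, with 1 marker per scaling (TMM, DESeq2 size factors, library totals alone). The nuclear condensation list stayed above 0 at the last 2 steps under each scaling, while the ribosomal protein and X-linked lists changed sign with library totals at the step to elongating spermatids.

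The X chromosome is silenced in male meiosis, and its share of counts was compared within libraries. X-linked genes gave 2.03% ± 0.434 of X-linked and autosomal counts in spermatogonia and 0.173% ± 0.0673 in spermatocytes, lower in 19 of 19 libraries by 1.85 points. The share rose to 1.46% ± 0.262 in round spermatids, from 0.178% ± 0.0689 in the spermatocytes of the same 20 libraries, and to 2.11% ± 0.231 in elongating spermatids from 1.48% ± 0.238, each in 20 of 20 libraries. Two-sided exact sign flip tests gave p = 3.81e-06, 1.91e-06 and 1.91e-06, the smallest each design allows (adjusted p = 3.81e-06, 2.86e-06 and 2.86e-06 over 3 steps). In the gene test 207 of 331 X-linked genes fell from spermatogonia to spermatocytes and 52 rose (camera adjusted p = 1.71e-15; adjusted p = 0.273 with an estimated correlation). For the step to elongating spermatids the mean log2 CPM of X-linked relative to autosomal genes gave +0.12 over all libraries, higher in 14 of 20, and -0.06 in the 6 whole-testis libraries, lower in 6 of 6, where the share of counts was higher in 6 of 6.

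**Figure D3:**
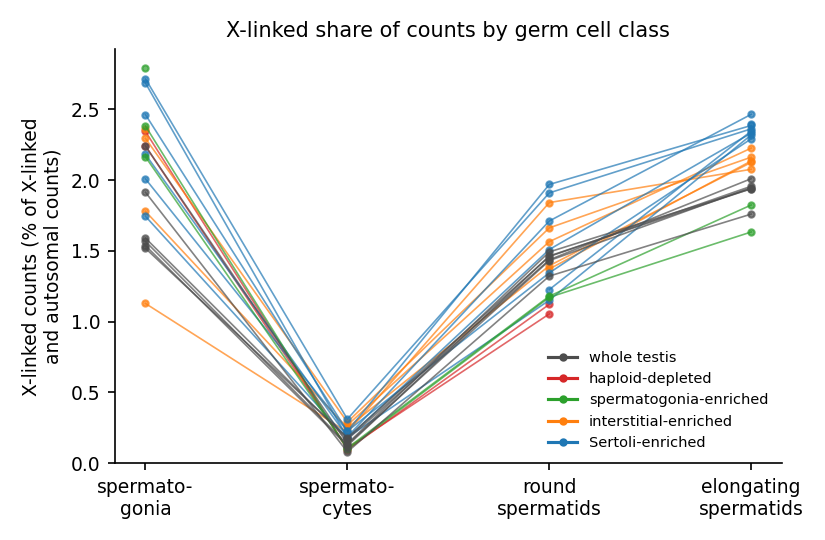
Percent of X-linked and autosomal counts that came from X-linked genes in each germ cell class, with lines joining classes of 1 library. The share fell from 2.03% to 0.173% between spermatogonia and spermatocytes and was higher again in round and elongating spermatids.

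The RNA counted per cell differed between germ cell classes. Median UMIs per cell rose from 1619 ± 662 (SD, n = 19 libraries) in spermatogonia to 7228 ± 3045 in spermatocytes, higher in 18 of 19 libraries. They fell from 7193 ± 3997 (n = 20) in round to 2148 ± 457 in elongating spermatids, lower in 19 of 20 (two-sided exact sign flip tests, p = 7.63e-06 and 9.54e-06, adjusted p = 1.43e-05 for both). Spermatocytes and round spermatids did not differ by this test (7345 ± 3010.1 against 6636 ± 3172, exact p = 0.375). In cells of at least 1000 UMIs, thinned to that number, median genes per cell were 772 ± 10.8 in spermatogonia and 748 ± 6.15 in spermatocytes (exact p = 1.14e-05). They were 748 ± 6.34 in spermatocytes and 767 ± 14.5 in round spermatids (exact p = 8.20e-05), and 765 ± 14.2 in round and 548 ± 22.0 in elongating spermatids (exact p = 1.91e-06, lower in 20 of 20). Without thinning the first was 1087 against 2769 genes, the second 2802 against 2602 (exact p = 0.139) and the last 2672 against 907.

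Somatic classes were each compared with the mean of the other 4 tested classes over 5551 genes, and the authors' class names and these contrasts rest on the same counts. Sertoli cells, part of each contrast, shared a library with another class only in Sertoli-enriched replicate 4, in sums of at least 20 cells. With the library block this limits the precision of the contrasts, so a gene not called may still differ. Endothelial cells, which line blood vessels, expressed 13 of 13 endothelial genes above the other classes (median log2 change 8.47; camera adjusted p = 1.57e-11; adjusted p = 0.424 with an estimated correlation). Abcb1a, a drug efflux pump of vessel walls (chromosome 5, 8660077 to 8748575), reached 1583 ± 507 CPM (n = 5 libraries), 10.55 ± 0.39 above the other classes on the log2 scale, Rgs5 1210 ± 1042, Ptprb, a phosphatase of endothelial junctions, 1446 ± 354 and the transcription factor gene Erg 412 ± 101. The chemokine gene Cxcl12 (1595 ± 671 CPM) and Kitl, the ligand of Kit (log2 change 1.17), were among 4 of 13 niche ligands that were higher. Of the 13, 1 was lower, and the list did not pass (median -0.20; adjusted p = 0.168). Of 18 dissociation stress genes 12 were higher (adjusted p = 1.67e-06; adjusted p = 0.424 with an estimated correlation), Fos at 3386 ± 2010.4 CPM, as were 5 of 8 myoid genes (adjusted p = 0.0489; adjusted p = 0.424 with an estimated correlation). In all 720 genes were higher and 515 lower.

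Leydig cells expressed genes of testosterone synthesis. Cyp17a1, which makes androgen precursors (chromosome 19, 46667165 to 46673172), was at 10368 ± 4749 CPM (n = 4 libraries) against 9.84 in the mean of the other classes, a log2 change of 11.37 ± 1.64, and Cyp11a1, which starts steroid synthesis from cholesterol, at 3736 ± 1969 (log2 change 8.16). Lcn2, an iron-carrier protein gene, was higher by 8.68 ± 0.35 and Klk1b24 by 10.52. Of 16 steroidogenesis genes 5 were called higher (camera adjusted p = 0.0703), while Insl3 (6617 ± 6617 against 23.5 CPM) and Fabp3 (6050 ± 2944 against 309.6 CPM) were not called. The count was 418 higher and 305 lower, 320 and 409 with library totals, and 863 and 642 with no library block. Macrophages, with 2 libraries, expressed Tyrobp, a signalling adaptor of myeloid cells, at 1209 ± 391 CPM (log2 change 10.25 ± 1.77), Cd74, a chaperone of antigen presentation, at 2434 ± 634 (8.18 ± 0.88), Gpr65 (8.51) and Slc40a1, an iron exporter (8.28). Of 17 macrophage genes 5 were called higher (adjusted p = 0.144), with Apoe at 16663 ± 3499 CPM, and Lyz2 was at 9383 ± 3794 against 17.5 CPM but not called. Their count was 286 higher and 92 lower, 168 and 26 with DESeq2, and 734 and 143 with no library block. In macrophages 0 of 4 innate lymphoid and T cell genes and 0 of 5 erythrocyte genes were called.

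Sertoli cells expressed Cst9, a cystatin (chromosome 2, 148835147 to 148838738), at 3598 ± 1239 CPM (n = 9 libraries) against 3.06 in the mean of the other classes, Clu, a secreted chaperone, at 8403 ± 2647 against 786.3 and Reep1 at 474 ± 127 against 4.95. Slc52a3, a riboflavin transporter, and Daam2 were also called higher. Of 20 Sertoli genes 6 were called higher (camera adjusted p = 0.00784; adjusted p = 0.408 with an estimated correlation), and of 18 dissociation stress genes 14 were lower (adjusted p = 1.34e-11; adjusted p = 0.321 with an estimated correlation), Fos by -5.18. Ribosomal protein genes were lower in 68 of 84 cases (adjusted p = 6.52e-51; adjusted p = 0.149 with an estimated correlation). Nuclear condensation transcripts of spermatids were higher in 8 of 17 cases (adjusted p = 2.55e-05; adjusted p = 0.408 with an estimated correlation), Prm2 by 1.62. In all 262 genes were higher and 386 lower, 82 and 278 with DESeq2, and 969 and 698 with at least 10 cells per sum. Within libraries this contrast rested on the Sertoli-enriched replicate 4, whose 21 endothelial cells were its link to the other classes, and without the library block 1572 genes were higher and 1367 lower.

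The unknown somatic cells expressed genes of connective tissue. Dcn, a collagen-binding proteoglycan (chromosome 10, 97479609 to 97518143), was at 12336 ± 4430.1 CPM (n = 12 libraries) against 802.9, a log2 change of 6.84 ± 1.01, Mgp, an inhibitor of matrix calcification, at 4046 ± 793 against 371.8 (6.25 ± 0.44), Adamts5, a matrix protease, at 2054 ± 478 and Cacng4 at 133 ± 77.3. Of 14 interstitial mesenchyme genes 8 were higher, Gsn by 4.47 and Col1a2 by 4.15 (camera adjusted p = 3.04e-06; adjusted p = 0.313 with an estimated correlation), and of 8 genes of the contractile machinery of myoid cells 6 were higher, Tpm1 by 1.97 (adjusted p = 0.000448; adjusted p = 0.273 with an estimated correlation). Pdgfra, a growth factor receptor of mesenchymal cells, was at 578 ± 116 against 82.5 CPM and was not called. Niche ligands were higher in 4 of 13 cases, Cxcl12 by 3.02 (adjusted p = 0.0325; adjusted p = 0.273 with an estimated correlation), stress genes in 13 of 18 (adjusted p = 5.70e-08; adjusted p = 0.313 with an estimated correlation), and cell cycle genes were lower in 4 of 7, Top2a by -5.31 (adjusted p = 0.00302; adjusted p = 0.273 with an estimated correlation). In all 405 genes were higher and 276 lower.

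The next comparisons asked whether a class differed between selected and whole-testis libraries. Spermatogonia from enriched libraries (n = 3) carried fewer transcripts of spermatids than those of whole testis (n = 6). Tulp2, Gsg1 and Oaz3, all genes of the haploid phase, were at 6.43 ± 6.15, 5.78 ± 5.30 and 6.77 ± 4.20 CPM against 114 ± 41.4, 76.4 ± 18.8 and 92.7 ± 34.1, log2 changes of -5.08 ± 0.65, -4.81 ± 0.61 and -4.17 ± 0.49 (edgeR adjusted p = 0.00825 each). Gpx4, which reduces lipid peroxides, gave -2.31, Dbil5 -2.80 and Prm2 -4.48, from 610 ± 213 to 40.0 ± 33.1 CPM (adjusted p = 0.0325), while Prm1, at 79.9 against 666 CPM, was not called (adjusted p = 0.0968). Med21, a subunit of the Mediator complex (chromosome 6, 146642547 to 146650732), rose by 0.99 ± 0.17, from 101 ± 16.1 to 213 ± 22.9 CPM. Of 12 nuclear condensation genes 4 fell over all genes tested and 11 adjusted over the list alone (camera adjusted p = 1.26e-19; adjusted p = 0.216 with an estimated correlation). Of 12 differentiating spermatogonia genes none was called and 2 rose adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.405 with an estimated correlation). Of 4 undifferentiated spermatogonia genes none was called (adjusted p = 0.876), and Id4 gave -1.65 (adjusted p = 0.297).

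Of 5717 genes 2 were higher and 18 lower in enriched libraries by edgeR, 1175 at an unadjusted p under 0.05, and 14 higher and 126 lower by DESeq2. With library totals 5 were higher and 18 lower. Without spermatogonia-enriched replicate 1, 233 genes were called, without replicate 2, 54, and without replicate 3, the Kit library, 38. Whole testis held 9.91% elongating spermatids and the enriched libraries 3.14% ± 2.51 (n = 3).

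Spermatocytes from haploid-depleted libraries (n = 2) differed from those of whole testis (n = 6) in listed transcripts of spermatids and of the cell cycle. Neither list call held with an estimated correlation. Of 20 nuclear condensation genes 17 fell and 1 rose, 18 and 2 adjusted over the list alone (camera adjusted p = 3.63e-11; adjusted p = 0.47 with an estimated correlation), Prm1 from 249 ± 113 to 21.9 ± 25.2 CPM (log2 change -3.24 ± 0.66, edgeR adjusted p = 0.00891) and Prm2 by -3.75. Of 16 cell cycle genes 9 rose and 1 fell (adjusted p = 0.000187; adjusted p = 0.139 with an estimated correlation), Birc5, which acts in chromosome segregation, by 0.50, Top2a by 0.41 and Ccnb2 by 0.34. Of 28 meiotic prophase genes 4 rose and 8 fell (adjusted p = 0.161). The histone gene Hist1h2al (chromosome 13, 51202727 to 51203065) was at 115 ± 16.7 CPM against 0.570 ± 0.382, Vnn1, a pantetheinase, at 45.3 ± 1.98 against 0.105 ± 0.143, Rab3c at 35.9 ± 2.14 against 0.482 ± 0.233, and Apoc2 and Dnajc25 also rose, by 5.28 and 2.17. Hoxb5os (-1.48), Fxyd2 (-2.05), Aknaos (-1.19), Sox6 (-1.12) and Rpl21 (-0.80) fell. Histone genes and Rpl21 have near-identical copies, and Hoxb5os and Aknaos are antisense to other genes, so their counts are uncertain.

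In all 1213 genes rose and 959 fell among 12611 tested, and with library totals 556 rose and 1517 fell, at a median over all genes of -0.20 instead of -0.05. Without haploid-depleted replicate 1 the count fell from 2172 to 231, and without replicate 2 it was 1275. The lone haploid-depleted library left is assumed to vary like those of whole testis, whose spread alone these tests use.

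Sertoli cells from enriched libraries (n = 8) against whole testis (n = 5) were compared in sums of at least 10 cells. Of 3247 genes edgeR called 4, all higher, with 296 at an unadjusted p under 0.05 and 20 called by DESeq2, 5 higher and 15 lower. EGFP, the fluorescent reporter the cells were sorted for, was at 239.5 ± 69.0 CPM against 0 counts in 105434 UMIs, at least 8.42-fold higher than the floor of 3 counts over the group. The labels name no reporter for whole testis, so this difference may come from the transgene itself and not from a change in Sertoli cells. Vcp-rs (chromosome X, 104345829 to 104348234), a copy of Vcp whose reads are hard to assign, was at 138 ± 46.2 CPM against 0 counts, at least 4.83-fold higher. The others, Gm11942 (adjusted p = 0.0382) and Gm15459 (adjusted p = 0.0382), are gene models named after their values were seen. Both also differed in spermatocytes, Gm11942 at 229 ± 137 CPM in Sertoli-enriched libraries against 1.38 ± 1.09 in whole testis. Gm15459 was at 21.8 ± 14.2 against 0.0415 ± 0.0648 there, so these differences were not confined to Sertoli cells. Of 20 Sertoli genes none was called (median 0.25; camera adjusted p = 0.0338; adjusted p = 0.487 with an estimated correlation), with Clu at 0.13. Without whole-testis replicate 6 no gene was called, and without replicate 2, 3 or 5 1 was. Leydig cells from interstitial-enriched (n = 5) against whole-testis libraries (n = 2) gave 0 of 751 genes by edgeR, 37 at an unadjusted p under 0.05 and 1 by DESeq2, and 0 of 14 steroidogenesis genes (median 0.04; adjusted p = 0.998). Without a filter on low counts 7 Leydig genes were higher. In libraries with shared replicate numbers alone, with no block, 10 were higher and 11 lower.

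Transcripts of other classes were counted in each class as a measured background. The Sertoli genes counted were list members under 2% of their Sertoli level in whole-testis spermatocytes, round and elongating spermatids. Their level in spermatogonia was not limited. In Sertoli-enriched libraries the Sertoli genes gave 82.3 ± 36.1 UMIs per Sertoli cell (SD, n = 8), 6.42 ± 3.07 per spermatogonium, 6.43 ± 6.22 per spermatocyte, 4.26 ± 3.16 per round spermatid and 2.59 ± 1.93 per elongating spermatid. In whole testis Prm1, Prm2, Tnp1 and Tnp2 together gave 379 ± 25.8 UMIs per elongating spermatid (n = 6), 7.51 ± 3.59 per spermatocyte, 3.24 ± 0.945 per spermatogonium and 28.0 ± 23.5 per Sertoli cell. Elongating spermatids took 42.5% ± 7.85 of cells in Sertoli-enriched libraries (n = 8) and 9.91% ± 1.33 in whole testis (n = 6), and all 8 lay above the whole-testis libraries (two-sided exact permutation test, p = 0.000666, the smallest possible).

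**Figure D4:**
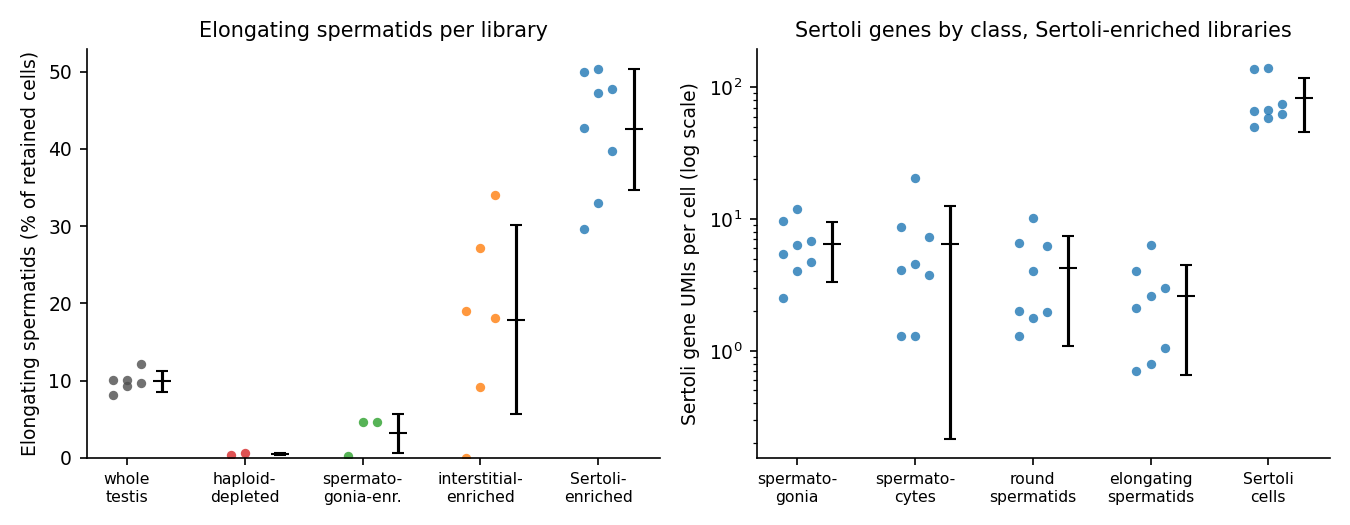
Left, elongating spermatids as a percent of retained cells, with 1 point per library in each group. Right, UMIs of Sertoli genes per cell (log scale) by class in the 8 Sertoli-enriched libraries, from a mean of 82.3 in Sertoli cells to 2.59 in elongating spermatids.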

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

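The test of shallow barcodes and the splits of libraries between groups were chosen only after the results were seen, as were the comparison of elongating spermatids, the ages, the share among other genes and the transcripts of Prm1, Prm2, Tnp1 and Tnp2 in haploid-depleted libraries, unknown somatic cells and Sertoli cells.

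Of 86 sets of library values examined, 14 held a library far from the others of its group, where 5% of independent sets with normal spread would give 4.3. The Sertoli-enriched replicate 1 had the highest median UMIs per cell of its group (6343), replicate 7 the highest share of round spermatids (39.3%) and of genes per spermatogonium at 1000 UMIs (789.5), replicate 5 of Leydig cells (0.546%), replicate 2 of unknown somatic cells (0.621%) and replicate 4 of endothelial cells (2.93%) and of all interstitial classes (3.49%). The interstitial-enriched replicate 2 had the highest shares of Leydig (25.7%) and endothelial cells (14.3%), and replicate 6 of macrophages (6.61%). In whole testis, replicate 4 alone held macrophages (0.0423%), and replicate 3 had the lowest X-linked percent in round (1.32%) and elongating spermatids (1.76%) and the most round spermatids per spermatocyte (1.34). These shares are of cells the authors assigned, and no cause was tested. Shares of rare classes rest on very few cells and the sets overlap, so the number given by chance is only a rough guide.

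The fall in genes per cell at 1000 UMIs from round to elongating spermatids differed between groups. It was -195.8 ± 10.2 genes (SD, n = 7) in Sertoli-enriched and -222.1 ± 7.54 (n = 6) in whole-testis libraries, a difference of 26.3 genes (two-sided exact permutation test, p = 0.00117, the smallest possible, adjusted p = 0.0210 over 18 tests).

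Barcodes outside the authors' annotation held cells that pass the authors' limits on genes and mitochondrial counts. There were 537 of them, all in the interstitial-enriched replicate 6, with 6451719 UMIs. Prm1 was at 14601 CPM in them and 1197.4 in the retained cells of that library, and Dcn at 319.6 and 10210 CPM. Nuclear condensation genes took 6.04% of their counts, 0.480% in the retained cells and 4.58% in the other interstitial-enriched libraries, and interstitial mesenchyme genes 0.107% and 3.01%. Counting these barcodes, the excess of interstitial classes over whole testis was 36.3 points rather than 40.7.

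Elongating spermatids took 42.5% of cells in Sertoli-enriched libraries and 9.91% in whole testis. Among cells with at least 2000 UMIs the shares were 41.6% and 5.89%, a ratio of 7.07. This argues against shallow barcodes in Sertoli-enriched libraries as the whole cause. It cannot test a loss of shallow whole-testis cells to the authors' filter, as the cut itself removes shallow cells. The 6 Sertoli-enriched libraries of 7 to 9 weeks each held at least 29.6%, against at most 12.2% in the 6 of whole testis at 7 and 9 weeks. This argues against age as the whole cause. Elongating spermatids of these libraries also carried Sertoli genes, by a median of 0.602 times as many UMIs per cell as round spermatids (range 0.402 to 1.06). This argues against Sertoli fragments held to elongating more than to round spermatids, while fragments held to both cannot be told apart. Against spermatocytes the ratio was 0.547 (0.0913 to 0.808, under 0.5 in 3 of 8 libraries) and against spermatogonia 0.313 (0.176 to 0.665, 6 of 8). The rule set beforehand asked for at least 7 of 8 libraries against spermatocytes and was not met. Elongating spermatids held the least of the germ cells in 7 of 8 libraries, but free RNA cannot be told apart from other sources. Cells classed as Sertoli held Prm1, Prm2, Tnp1 and Tnp2 at a median of 1.94 times the UMIs per spermatogonium and 1.04 times those per spermatocyte in these libraries (exact sign flip tests, p = 0.0391 and 0.867), and 8.64 and 3.22 times in whole testis, on 5 to 17 Sertoli cells each (p = 0.0938 and 0.188), so attached elongating spermatids stay open, as does the sort for a Sertoli reporter, which was not tested.

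Spermatogonia and spermatocytes of whole testis held transcripts of Prm1, Prm2, Tnp1 and Tnp2, at 3.24 ± 0.945 and 7.51 ± 3.59 UMIs per cell (SD, n = 6). In the 2 haploid-depleted libraries these were 0.219 and 0.0476 per spermatogonium and 0.150 and 1.00 per spermatocyte. For spermatogonia this argues against transcripts made in these cells as the whole cause, on 2 libraries and with no test. For spermatocytes the values do not decide, as a change in their stages between the groups was not tested. UMIs per spermatogonium were 0.447 times those per spermatocyte (median of 6 libraries, range 0.269 to 1.03), where free RNA alone would give like values, and the Prm1 percent of the 4 genes differed by 5.76 points from that in elongating spermatids (range 2.40 to 8.54). Unknown somatic cells held 0.238 times the UMIs per spermatocyte (range 0.168 to 0.449, 6 of 6 libraries; exact sign flip test, p = 0.0313, the smallest possible), which argues against free RNA as the whole source in spermatocytes. In spermatogonia neither of the other values decides, so free RNA of elongating spermatids cannot be told apart from doublets.

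Of 29 genes at least 16-fold higher in spermatocytes of haploid-depleted than of whole-testis libraries, 65.5% were at least 4-fold higher in spermatocytes of Sertoli-enriched libraries too, which had no haploid depletion. Against the same whole-testis libraries this held for 0.796% of 5025 other genes that were not called higher and had at most 9.97 CPM in whole testis. Part of this contrast is built in, as the same whole-testis values picked the 29 genes and the other genes leave out those called higher. For the genes higher in both groups, the values argue against the haploid depletion itself as the whole cause. Of the 29 genes 27.6% were at least 4-fold higher in spermatogonia and 55.2% in round spermatids. A difference between animals, or in how reads were assigned, that acts in every class cannot be told apart from one that acts in spermatocytes. A strain or transgenic background may differ between libraries and was not tested.

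The germ cell and somatic classes were made from the same counts, so splits of their sums cannot test chance. In the germ cell steps 1 of 50 splits of each, the real one, gave as many genes in a fit of the 2 classes alone: 4432 genes against at most 3548 in the others for spermatogonia and spermatocytes, 6968 against 5961 for spermatocytes and round spermatids and 4266 against 3431 for round and elongating spermatids. The highest of the other splits exchanged 3 libraries. For the somatic classes 1 of 30 splits gave as many, 1235 genes against at most 6 for endothelial cells, 723 against 3 for Leydig cells, 378 against 1 for macrophages, 648 against 8 for Sertoli cells and 681 against 0 for unknown somatic cells. Between groups few splits, the real one included, gave as many genes for spermatogonia (2 of 84 splits, 20 genes) and unknown somatic cells (1 of 100, 27 against at most 19). The same held for elongating spermatids (1 of 100, 1055 against at most 248). These splits were chosen after the results were seen, and the labels do not tie libraries to animals, so they do not exclude chance. For spermatogonia the split of whole-testis replicate 1 with the enriched replicates 2 and 3 gave 267 genes, more than the real split, and the cause was not tested. For Sertoli cells 5 of 100 splits gave at least the 4 genes called, at most 167.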

How the results depend on the processing

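Chosen only after the data were seen were the subsets by spike-in species, library totals without a scaling factor, shared replicate numbers without a block, the share without interstitial-enriched replicate 6, the left-out barcodes, and each alternative for unknown somatic cells and elongating spermatids between groups. Of 4164 values over 604 results, 3714 kept their side of the threshold (counts within 1.5 times), 182 passed no longer, 207 passed newly, 46 counts or values moved further and 15 reversed. For genes and per-cell values, a change of sign counted as reversed only where the value passed with the alternative or without it. The 3714 may therefore hold values that changed sign without passing. Where no cause is named below, the cause was not tested.

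Without thinning, median genes per cell reversed to 1682 more in spermatocytes than in spermatogonia and to -201 from spermatocytes to round spermatids (exact p = 0.139). The cause was not tested. In whole-testis and haploid-depleted libraries alone Zbtb16 reversed to -4.04 (log2) from round to elongating spermatids. With at least 10 cells per sum these reversed: Dcn in Leydig cells to -2.55, in Sertoli cells Aldh1a1 to -1.05 and Rora to 1.12, and in unknown somatic cells Aldh1a1 to 2.06 and Cyp17a1 to -3.23. With no library block Pdgfra reversed in macrophages to 1.74 and in Sertoli cells to -3.29, Aldh1a1 in Sertoli cells to -2.04, Rora to 1.88 and Cyp26b1 to -1.91, and in unknown somatic cells Aldh1a1 to 1.80 and Cyp17a1 to -2.87. The cause was not tested.

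Among shares, the excess of spermatogonia in cells with at least 1000 UMIs was 31.03 points and passed (exact p = 0.0476, unadjusted). With fewer libraries, where the smallest p cannot pass, the excess was 34.6 (human spike-in) and 53.1 points (no spike-in) for interstitial classes and 21.01 (human spike-in) for Sertoli cells. Leaving out 1 library gave -33.2 to -19.3 points for the haploid-depleted group, 2.34 to 43.2 for the spermatogonia-enriched group and, without interstitial-enriched replicate 6, 29.6 for the interstitial classes.

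Without a filter on low counts, where more genes are tested, counts moved to 12456, 13492 and 10232 for the 3 germ cell steps, 452 for Leydig and 322 for Sertoli cells among somatic classes, and between groups to 1707 for spermatogonia, 172 for Sertoli cells, 7 for Leydig cells, 430 for unknown somatic cells and 1866 for elongating spermatids. By adjusted p alone 9079 genes were called between spermatocytes and round spermatids. DESeq2 gave 194 genes for macrophages and 360 for Sertoli cells among somatic classes, and between groups 140 for spermatogonia, 20 for Sertoli and 1 for Leydig cells. Its size factors in edgeR gave 2 for Sertoli cells between groups. With at least 10 cells 781 genes were called for endothelial and 1667 for Sertoli cells, and with no library block 1505 for Leydig cells, 877 for macrophages, 2939 for Sertoli and 1108 for unknown somatic cells. The cause was not tested.

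Leaving out 1 library gave 38 to 233 genes for spermatogonia between groups (without replicate 3 and 1), 231 to 1275 for spermatocytes (without replicate 1 and 2) and 0 to 3 for Sertoli cells (0 without whole-testis replicate 6, 1 without 2, 3 or 5). For spermatocytes the lone haploid-depleted library left is assumed to vary like those of whole testis, whose spread alone the test uses. The replicate block gave 0 genes for spermatogonia, 2 for Sertoli cells and 17 for unknown somatic cells, and the same libraries without the block 0 for spermatogonia and 21 for Leydig cells. Libraries with no spike-in gave 85 genes for spermatogonia and 87 for unknown somatic cells, and those with human spike-in 0 for unknown somatic cells and 34 for elongating spermatids. With at least 50 cells, hence fewer sums, unknown somatic cells gave 0. Replicate numbers did not pair the samples: the highest correlation was with the same number in 4 of 24 cases.

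Thinned to the smallest sum, Sertoli cells gave 2 genes rather than 4, unknown somatic cells 4 rather than 27 and elongating spermatids 409 rather than 1055, while spermatogonia gave 35 rather than 20. Not run were somatic classes with at least 50 cells, Sertoli and Leydig cells between groups with more cells per sum, and macrophages between groups, which had no whole-testis sums.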

Other observations

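The comparisons of unknown somatic cells and of elongating spermatids between groups were chosen only after the classes and shares had been seen.

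Elongating spermatids from Sertoli-enriched libraries (n = 8) carried more Sertoli transcripts and fewer meiotic transcripts than those of whole testis (n = 6). Of 8 Sertoli genes 8 rose (camera adjusted p = 3.67e-08; adjusted p = 0.134 with an estimated correlation), Defb19, a defensin of Sertoli cells, from 16.5 ± 12.5 to 199 ± 158 CPM and Clu from 8.79 ± 5.49 to 111 ± 82.3. Of 14 meiotic prophase genes 7 fell (adjusted p = 1.27e-05; adjusted p = 0.134 with an estimated correlation), Sycp1 by -1.97 and Sycp2 by -2.03 on the log2 scale. Of 96 X-linked genes 31 rose and 2 fell (adjusted p = 1.27e-05; adjusted p = 0.134 with an estimated correlation). Smco2 (chromosome 6, 146850104 to 146871406) rose from 59.2 ± 8.78 to 499 ± 125 CPM (log2 change 3.01 ± 0.18, edgeR adjusted p = 8.34e-10) and Ppp4r2, a phosphatase subunit, by 2.95. Bloc1s6 was at 128 ± 36.4 CPM with 1544 counts against 3 counts, and Yjefn3 at 65.7 ± 27.1 CPM with 894 counts against 1 count. Pabpc1, which binds the tails of messenger RNA, fell from 1023 to 465.7 CPM. Serp2 (-1.58), Rpl26 (-0.89) and Prm1 (-0.40) also fell. In all 564 genes rose and 491 fell of 4363, 523 and 524 with DESeq2 size factors, 657 and 411 with library totals, 34 in libraries with human spike-in alone.

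Unknown somatic cells from interstitial-enriched libraries (n = 6) differed from those of whole testis (n = 6) in a number of genes that moved with the libraries and the filter. Cox8c, a testis form of a cytochrome oxidase subunit (chromosome 12, 102899316 to 102900526), fell from 412 ± 64.8 to 57.1 ± 44.4 CPM (log2 change -3.22 ± 0.41, edgeR adjusted p = 0.000313), as did Lyar (-2.08), Ldhc (-2.18), Cfap36 (-1.49), Fam104a (-1.32) and Usp1 (-1.17). Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), rose from 217 ± 40.1 to 521 ± 141 CPM and Bclaf1 by 0.92. Of 7 nuclear condensation genes 1 fell, 2 adjusted over the list alone (median -0.52; camera adjusted p = 0.0231; adjusted p = 0.451 with an estimated correlation). X-linked genes were higher as a list, a call that held with an estimated correlation (median 0.32; camera adjusted p = 0.000748; adjusted p = 0.0144 with an estimated correlation), with 0 of 37 called by edgeR. Of 14 interstitial mesenchyme genes none was called (adjusted p = 0.0863). In all 2 genes rose and 25 fell of 1066, 172 at an unadjusted p under 0.05, 5 and 23 with DESeq2 size factors, and 0 were called in libraries with human spike-in alone. In libraries with no spike-in 45 rose and 42 fell, and without a filter on low counts 248 rose and 182 fell. The interstitial-enriched libraries were of 9 to 18 weeks and those of whole testis of 7 and 9 weeks, and age was not tested.

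The ratio of elongating to round spermatids was 2.47 ± 0.955 in Sertoli-enriched libraries (n = 8), 0.988 ± 0.533 in interstitial-enriched libraries (n = 5) and 0.255 ± 0.0480 in whole testis (n = 6; two-sided exact permutation tests, p = 0.000666 and p = 0.00433, each the smallest possible). Round spermatids per spermatocyte were 2.78 ± 1.07 in Sertoli-enriched libraries, 2.57 ± 1.13 in interstitial-enriched libraries (n = 5) and 1.02 ± 0.168 in whole testis (two-sided exact permutation tests, p = 0.000666, the smallest possible, and p = 0.0130). These 5 interstitial-enriched libraries were of 10 to 18 weeks and those of whole testis of 7 and 9 weeks. Age and selection cannot be told apart between them.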
